A study of Drosophila melanogaster with 23 samples.

How the data were processed

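The labels describe 23 RNA-seq libraries of whole embryos collected over a short egg-laying period, with total RNA made into libraries by a kit for Drosophila RNA. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.2b, HTSeq 0.10, DESeq2 and RSEM 1.3.1, and the genome build dm6. The notes give no order or role for these tools. The 2 deposited tables are, by their titles, gene counts normalised by a size factor and TPM.

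Samples were assigned to 8 groups of genotype and age from their titles. For the oldest embryos, one label field gives a different start of the age window from the title, and the title was used. Each table has 23 value columns, and none of its 17493 lines is a header or names a sample. The 23 columns of each table, 46 in all, could not be matched to a sample by name and were not used. The planned comparisons of genotype at each age, of age within genotype, of fixed gene lists and of a developmental score were therefore not run, and no depth, error or p-value is given.

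Only the gene identifiers were used. They were matched to the Ensembl release 115 gene annotation of the BDGP6 assembly for symbol, biotype and position, with positions counted from 1. Replication-dependent histone genes were taken as the genes whose symbol begins with His1, His2A, His2B, His3 or His4 followed by a colon. The 38 gene lists were fixed before the data were examined. Of these, 36 name their members, and the other lists, of replication-dependent histones and of ribosomal proteins, are defined by a symbol pattern. Members were matched by current symbol or, failing that, by an alias written into the list or by a RefSeq synonym that belongs to 1 gene. The aliases were not checked to name the same gene as the member. Of 635 named entries, 627 were matched to a row, and the remaining 8 are not analysed here. Whether entries of a list shared a row was not checked.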

Results

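RNA was sequenced from whole Drosophila melanogaster embryos of 2 genotypes at 4 ages after egg laying. The wild type strain w1118 gave 12 libraries, and embryos with the deficiency Df(2L)HisC on both second chromosomes, a deletion of the replication-dependent histone gene cluster, gave 11 libraries. The ages were 3.5 to 4 h, 4.5 to 5 h, 5.5 to 6 h and 6.5 to 7 h. Each of the 8 groups held 3 libraries, except the deletion embryos at 4.5 to 5 h, which held 2. The design text names a comparison of gene expression between wild type embryos and deletion embryos, which it describes as without newly made histones. That description was not tested here.

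No difference between the genotypes or between the ages is reported here. Both expression tables carried 23 value columns without any column name, and no line of either table named a sample. Assigning columns to libraries by their order or by their values would have been a guess, so no value column was used. Expression levels, library depths, fold changes and gene list tests are therefore not given, and what follows describes only the genes that the tables list.

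Both tables listed the same 17493 FlyBase gene identifiers. Of these, 17372 (99.31%) were found in the Ensembl release 115 annotation of the BDGP6 assembly, which has dm6 coordinates, and 121 were not. The identified genes comprised 13851 protein-coding genes, 2489 non-coding RNA genes, 316 pseudogenes, 312 tRNA genes, 258 snoRNA genes, 115 rRNA genes and 31 snRNA genes. The annotation held 13986 protein-coding genes and 312 tRNA genes, so nearly all of the former and all of the latter were listed. A listed gene was not thereby shown to be detected, because no value was used. By chromosome arm, 4120 lay on 3R, 3539 on 2R, 3412 on 2L, 3406 on 3L and 2599 on X. Chromosome Y held 113, chromosome 4 held 109 and the mitochondrial genome held 37. The other 37 lay on other sequences of the assembly.

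The annotated genes of the histone cluster had rows of their own in both tables. Whether the assembly holds every copy of the cluster was not checked. All 111 annotated replication-dependent histone genes were listed, namely 23 genes for the linker histone H1, 20 for H2A, 23 for H2B, 23 for H3 and 22 for H4. They all lay on chromosome 2L between positions 21416953 and 21541681, a span of 124729 bp. The same span held 26 other annotated elements, of which 24 were listed. The copies of each histone gene are nearly identical in sequence, so reads from one copy can be counted under another or discarded, and a row for a single copy is uncertain as a measure of that copy.

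Genes that supply or deposit histones outside the cluster were also listed. His2Av, which encodes the H2A variant H2Av, lay on 3R between 26866929 and 26869220. His3.3A, which encodes the replication-independent H3.3, lay on 2L between 5055058 and 5056149, outside the cluster. All 6 members of the list of replication-independent histones had a row under their current symbol. All 19 of the list of histone supply and chaperone genes were matched to a row, 18 of them by current symbol.

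Genes of the cell cycle, cell death and embryonic patterning were listed as well. The mitotic inducer stg, a Cdc25 phosphatase, lay on 3R between 29251826 and 29255800. All 33 members of the mitotic list were matched to a row, 32 of them by current symbol. For the DNA replication list, 37 of its 38 members were matched to a row, among them PCNA, the sliding clamp of the replicative polymerases, on 2R between 20261754 and 20262883. The pro-apoptotic genes rpr and hid both lay on 3L. All 19 entries of the apoptosis list were matched to a row, 18 of them by current symbol. Entries that share a row would each be counted. All 8 Hox genes were listed, including Ubx on 3R between 16656623 and 16734426 and Abd-B on 3R between 16927212 and 16972236. Of the list of other Polycomb target regulators, 73 of 74 members were matched to a row, and of the Polycomb group itself 18 of 19. These counts describe the match through the annotation. Because 13851 of 13986 annotated protein-coding genes were listed, near-complete lists are no result about these gene classes. An unmatched member could be a gene without a row, as were 135 annotated protein-coding genes. It could also stand under a symbol that the match did not recognise, or under one of the 121 identifiers not found in the annotation.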

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

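Both alternatives were chosen after seeing the data, and none of the alternatives planned beforehand was run, since each needs values assigned to samples. The number of gene identifiers found was 17372 with the Ensembl annotation and 17372 with a separate table of gene names. Each reference was searched by FlyBase gene identifier, and whether they are independent was not checked. The equal counts are therefore no test of the match. Of the 635 named list entries, 627 were matched to a row when list aliases and RefSeq synonyms were allowed and 598 by current symbol alone. No paired analysis was possible because the value columns carry no sample names or replicate numbers.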
